A study of Mus musculus with 24 samples.

How the data were processed

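Each of the 24 samples was RNA of the suprachiasmatic nucleus (SCN) pooled in equal amounts from 3 C57/BL6 mice. The mice were held in a light-dark cycle and then in constant darkness, and tissue was collected every 2 h from CT 18 to CT 64. Per the labels, RNA was amplified and biotin-labelled with NuGen Pico WTA V2 and Encore kits and hybridised to Affymetrix MoGene 1.0 ST arrays. The deposited values are log2 probe set intensities that the authors normalised across arrays by RMA (version 1.3.1.187 per the submitters' processing notes) in Affymetrix Expression Console. Background and summarisation settings were not stated. Array medians lay between 6.24 and 6.36 and no value was missing, and no further normalisation was applied in the main fits. The spread of values still differed between arrays, with interquartile ranges from 2.48 (CT 40) to 2.90 (CT 20). No genome build was given, so no coordinates are reported.

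The table held 35556 probe sets. The platform annotation listed 23410, of which 21789 had 1 gene symbol and 1621 several, and 12146 were not listed. Entrez identifiers of 21698 of the 21789 matched the RefSeq gene table of the assembly GRCm38.p6, used for names only, and 0 symbols changed. Each of 19938 genes was represented by the probe set with the highest mean (999 genes had more than 1). Genes with a mean below the 30th percentile (log2 5.52) were left out, and 13956 were tested.

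Arrays were grouped by time into the first cycle (CT 18 to CT 40, 12 arrays) and the second cycle (CT 42 to CT 64, 12 arrays), which hold the same 12 circadian times. Time entered as cosine and sine terms, and with 1 array per time the spread around the fit (21 residual degrees of freedom) was the error. Fits used limma 3.58.1 in R 4.3.3 with eBayes moderation and Benjamini-Hochberg adjustment, at a threshold of 0.05. The 24-h rhythm was a moderated F test of both 24-h terms. The change between cycles was a moderated test of a cycle term beside the 24-h terms, the change in rhythm a moderated F test of the interaction terms, and the 12-h rhythm a moderated F test of 12-h terms beside the 24-h terms. Tests were two-sided. Tables and figures were made with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The period of core clock genes was the value between 20 and 28 h, in steps of 0.1 h, with the smallest residual sum of squares.

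The tests, filter, threshold, 28 gene lists and the rule for named genes were set before the data were examined. Lists were tested by Fisher's exact test of called members against the other tested genes. That test takes genes as independent, while all were measured on the same 24 arrays, so its p-values may be too small. The mean of centred log2 values over members was tested by 100000 permutations of the 24 times, with a smallest p of 1e-05, and the shift between cycles by an exact paired sign-flip test with 4096 patterns. The same sign flips of the centred differences, a test not among those set beforehand, served for the change in rhythm of list means. The concentration of peak times was set against 10000 random sets of rhythmic genes, for the 14 lists with at least 3 rhythmic members. All were adjusted over the lists. Besides the lists named with their results in the report, lists of anterior pituitary markers and interferon-induced genes were added after seeing the data. Of the SCN identity and the G protein lists 4 members each are held by another list, as is 1 each of the core clock, immediate early, neighbouring neuron and pituitary lists. Some listed symbols had no probe set with a single symbol and were left out.

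The rule named every measured core clock gene. It also named the 12 called genes of largest amplitude with per-cycle peaks within 4 h, and up to 4 called members of each other list with the smallest adjusted p, or the 2 with the smallest p where none was called. For the other comparisons it named up to 8 genes of largest effect past the threshold or, where none passed, the 3 with the smallest p. Of the named genes 5 had more than 1 probe set above the filter, and 1 of these differed in the call.

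The fits were tested on simulated data of 13956 genes, with 66 or 67 genes changed at each size. The noise was drawn independently for each gene, without variation shared by the genes of an array, so the rates may differ in the real data. For the 24-h rhythm, 46.3% of genes with an amplitude of 0.15, 97.0% at 0.3 and 100% at 0.6 were recovered, and 6.9% of calls were false. For the 12-h rhythm 49.3%, 98.5% and 100% were recovered at these amplitudes. For the change between cycles 79.1% were recovered at 0.3 and 100% at 0.6 and 1.2, and for the change in rhythm 46.3% at 0.3 and 100% at 0.6 and 1.2. The rank test recovered 37.3%, 95.5% and 100% at amplitudes of 0.15, 0.3 and 0.6.

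Alternatives covered the filter (none, or the 50th percentile), all probe sets, quantile normalisation, median centring, array weights, a trended prior, the oligodendrocyte marker mean as a covariate, linear time or cycle as a covariate, periods of 23 and 25 h, a rank test in the manner of JTK_CYCLE, an ordinary F test, 24-h and 12-h terms together, linear values, each cycle alone, circadian time as a block, a linear slope, and each array left out in turn. Chosen after seeing the data were the fits without CT 40, CT 62 and CT 64, and those with covariates for meningeal markers, for meningeal and oligodendrocyte markers together, for pituitary markers, and for the array background. The array background was the mean over 1194 olfactory and vomeronasal receptor genes, 82 of them above the filter, and it correlated at r = -0.948 with the interquartile range across arrays.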

Results

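Transcript levels were measured in the suprachiasmatic nucleus (SCN), the hypothalamic pacemaker of daily rhythms, of C57/BL6 mice kept in constant darkness. The series holds 24 arrays, 1 every 2 h from circadian time (CT) 18 to CT 64, and each array carries RNA pooled from 3 mice. The first cycle, CT 18 to CT 40, and the second cycle, CT 42 to CT 64, hold 12 arrays each, with no replicate at any time, so the number of arrays limits the precision. Errors are standard errors of the cosine fit over 24 arrays, amplitudes are log2 units from mean to peak, and peak times are in hours of circadian time from 0 to 24. The array at CT 40 correlated less with the others (median r = 0.970) than the remaining 23 (0.987 to 0.991). The arrays at CT 40, CT 62 and CT 64, which fall at circadian times 14 and 16, had the narrowest spread of values, with interquartile ranges of 2.48, 2.67 and 2.65 against 2.72 to 2.90 in the rest. They also had the highest mean over 1194 olfactory and vomeronasal receptor genes, at 0.34, 0.19 and 0.16 above the series mean, a mean called the array background from here on.

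The first comparison asked which SCN transcripts rise and fall over 24 h without light. Most genes of the molecular clock did so. Nr1d1, a repressor of Arntl, peaked at 3.89 ± 0.36 h with an amplitude of 0.57 ± 0.05, a 2.21-fold change from trough to peak. Dbp, an activator of output genes, peaked at 7.29 ± 0.32 h (amplitude 0.43 ± 0.04, 1.81-fold), and Per2, a repressor of its own transcription, at 9.53 ± 0.28 h (amplitude 0.45 ± 0.03, 1.86-fold). Arntl, which encodes the partner of CLOCK, peaked nearly opposite to Per2 at 21.8 ± 0.81 h (amplitude 0.17 ± 0.04). Nfil3, a repressor at the sites that DBP activates, peaked near Arntl at 19.1 ± 0.50 h (amplitude 0.27 ± 0.04).

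Of the 18 measured genes of the core clock loop, 15 were called rhythmic among all genes tested and 18 when adjusted over the list alone (Fisher's exact test, odds ratio 61.2, adjusted p = 2.98e-13). Per1 peaked at 6.30 h, Per3 at 8.44 h and Cry1 at 10.3 h. Rora (5.94 h), Nr1d2 (6.04 h), Hlf (7.25 h), Cry2 (7.27 h), Ciart (7.62 h) and Tef (8.43 h) were also called, as was Rorb at 3.41 h. Bhlhe41, Bhlhe40 and Clock were not called, with amplitudes of 0.13, 0.10 and 0.09 and adjusted p of 0.0600, 0.133 and 0.182. The mean of the list had an amplitude of 0.18 ± 0.02 and peaked at 6.68 h (permutation p = 1e-05, the smallest that the permutations can give, adjusted p = 0.00028). Without the arrays at CT 40, CT 62 and CT 64, 14 of the 18 were called, since the adjusted p of Rorb rose to 0.0519, while its amplitude went only from 0.22 to 0.21. The period that best fitted each of the 15 called genes had a median of 24.1 h and ranged from 21.3 h for Nr1d2 to 26.4 h for Arntl. These genes had been called by a test at 24 h, which favours periods near 24 h. The 95% range for Per2, the most precise, was 23.4 to 25.3 h. The ranges of Arntl, Per1, Rorb and Ciart reached the upper search limit of 28 h. That of Nr1d2, 20 to 23.3 h, reached the lower limit and left out 24 h.

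**Figure D1:**
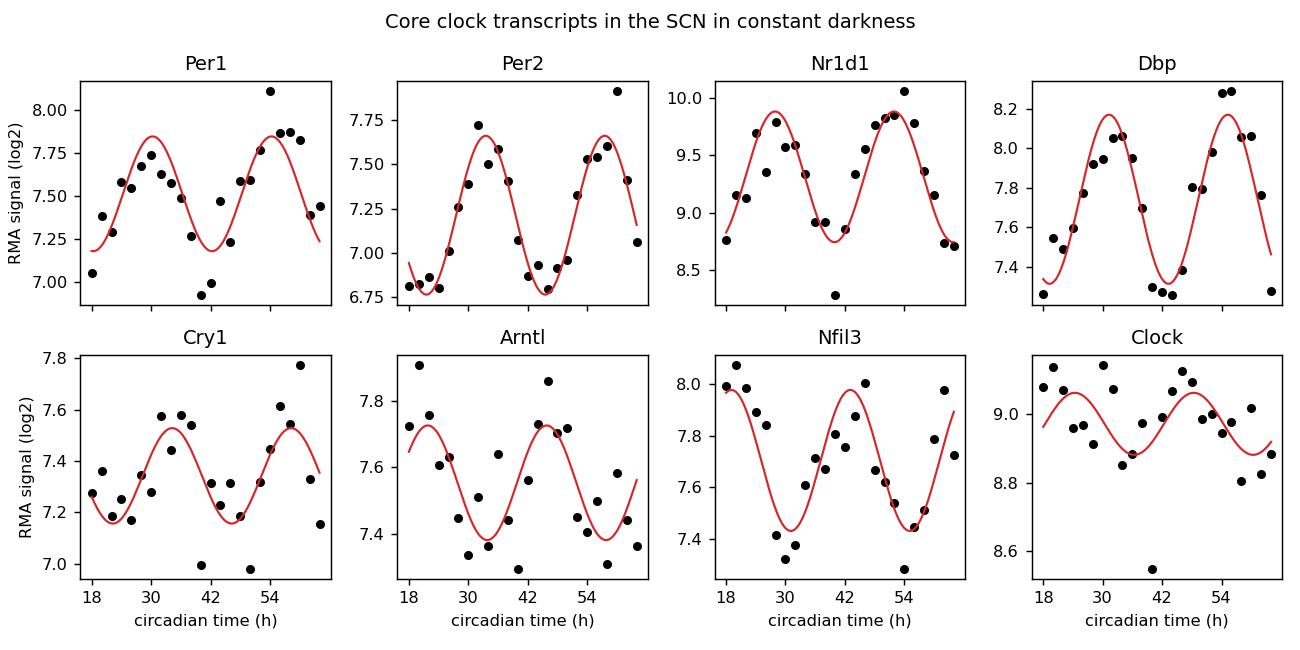
Levels (log2, vertical axes) of 8 core clock genes against circadian time in hours, with a dot for each of the 24 arrays and a line for the 24-h cosine fit. Per2 peaks at 9.53 h and Nr1d1 at 3.89 h of each cycle, and Arntl and Nfil3 peak at 21.8 and 19.1 h, while Clock did not pass the test.

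Among the called genes the largest amplitude was that of Rgs16, a regulator of G protein signalling, at 0.73 ± 0.06, a 2.73-fold change with a peak at 3.90 h. Rasl11b, a small GTPase, had an amplitude of 0.62 ± 0.04 and peaked at 4.13 h. Prok2, an SCN output peptide, had an amplitude of 0.55 ± 0.07 and peaked at 4.47 h. Fbxl21, a ubiquitin ligase subunit that acts on cryptochromes, Chrna3, a nicotinic receptor subunit, and Dusp4, a phosphatase of MAP kinases, peaked between 5.42 and 7.16 h with amplitudes of 0.51, 0.50 and 0.47. Of the 12 called genes with the largest amplitudes, others peaked near 14 to 16 h. These were the interferon-induced genes Ifit3 (0.64 ± 0.06), Ifit3b (0.58 ± 0.07) and Ifi27l2a (0.47 ± 0.09), together with Plekhf1 (0.50 ± 0.11) and Rasd1 (0.52 ± 0.10), a Ras-like protein of photic signalling. These peaks fall where the 3 arrays of narrow range sit. All 12 genes were also called without those arrays and with the array background covariate.

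Among SCN neuropeptides and their receptors, 4 of 22 genes were called (6 adjusted over the list alone; Fisher's exact adjusted p = 0.178). Besides Prok2 these included the vasopressin receptor Avpr1a, with an amplitude of 0.37 ± 0.07 and a peak at 17.3 h. The others were the VIP receptor Vipr2, with 0.38 ± 0.07 and a peak at 20.5 h, and Avp itself, with 0.36 ± 0.09 and a peak at 7.41 h. The call of Avp was lost in 16 of the fits that each left out 1 array (adjusted p = 0.0771 without CT 22, where its amplitude was 0.32 against 0.36 on all arrays). The list mean showed no rhythm (amplitude 0.02 ± 0.03, adjusted p = 0.835). Enrichment of this list did pass without the arrays at CT 40, CT 62 and CT 64 (5 called, adjusted p = 0.0124) and with the array background as a covariate (4 called, adjusted p = 0.0313), and at a threshold of 0.01 on the adjusted p of genes (3 called, adjusted p = 0.0129).

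Genes that mark SCN identity were enriched, with 7 of 21 called and 12 adjusted over the list alone (Fisher's exact adjusted p = 0.00209). Id2, a transcriptional inhibitor, peaked at 1.39 h (amplitude 0.27 ± 0.05), beside Rasl11b, Rgs16 and Rasd1, and was not called with the array background covariate (amplitude 0.16, adjusted p = 0.0584). The list mean peaked at 2.71 h (amplitude 0.10 ± 0.03, adjusted p = 0.0266). That call ended with the median of members (adjusted p = 0.0741), without the arrays at CT 40, CT 62 and CT 64 (0.228) and with the array background covariate (0.275). Of the immediate early and CREB target genes, 6 of 33 were called and 9 adjusted over the list alone (adjusted p = 0.0857). Sik1, a kinase that restrains CREB co-activators, peaked at 4.28 h (amplitude 0.38 ± 0.03), the nuclear receptor Nr4a3 at 3.0 h (0.25 ± 0.05) and Ier5 at 21.02 h (0.17 ± 0.04). Nr4a3 was not called without the arrays at CT 40, CT 62 and CT 64 (adjusted p = 0.0628) or with the array background covariate (0.0619). Their list mean did not pass (adjusted p = 0.116), and enrichment passed with no filter on dim genes (5 called, adjusted p = 0.0302). Of the kinases, phosphatases and ligases that act on clock proteins, 3 of 23 were called and 6 adjusted over the list alone (adjusted p = 0.629). Besides Fbxl21 these were Prkaa2, a subunit of AMP-activated kinase (5.91 h, amplitude 0.22 ± 0.05), and Ppp1ca (1.77 h, 0.23 ± 0.06). Ppp1ca lost its call in 14 fits that each left out 1 array (amplitude 0.21 and adjusted p = 0.0766 without CT 38). Ppp1ca was also not called without the 3 arrays of narrow range (0.138) or with the array background covariate (0.529). The mean of this list peaked at 3.66 h (adjusted p = 0.0279). That call ended with the median of members (0.115), with linear time as a covariate (0.0549) and without the arrays at CT 40, CT 62 and CT 64 (0.649). With the array background covariate the mean passed (0.0367) at an amplitude of 0.04 with a peak at 8.35 h.

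Several heat shock genes peaked in the subjective night. Hspa1a, the inducible HSP70 chaperone, peaked at 17.2 h with an amplitude of 0.45 ± 0.05, the co-chaperone Chordc1 at 19.0 h (0.29 ± 0.04), the HSP90 adaptor Stip1 at 21.4 h (0.21 ± 0.03) and Hsph1 at 22.2 h (0.30 ± 0.04). Of 22 heat shock and cold-inducible genes, 14 were called and 19 adjusted over the list alone (Fisher's exact adjusted p = 5.38e-10). Of these, 10 peaked between 18 and 24 h, 2 between 12 and 18 h and 2 between 6 and 12 h, not significantly closer together than random sets of rhythmic genes (adjusted p = 0.3002). The cold-inducible RNA-binding genes Cirbp and Rbm3, singled out after their values were seen, peaked on the other side of the cycle at 7.41 and 9.19 h (amplitudes 0.23 ± 0.05 and 0.36 ± 0.06). The list mean had an amplitude of 0.11 ± 0.02 with a peak at 19.7 h (permutation p = 2e-05, adjusted p = 0.00028).

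Of 21 genes of endoplasmic reticulum stress 7 were called and 11 adjusted over the list alone (Fisher's exact adjusted p = 0.00209). Of the 7, 6 peaked between 18 and 24 h, a concentration that did not pass (adjusted p = 0.160). The chaperone Calr peaked at 22.7 h (amplitude 0.19 ± 0.03), Sdf2l1 at 19.8 h (0.16 ± 0.04), the secreted factor Manf at 19.5 h (0.16 ± 0.03) and Creld2 at 16.6 h (0.25 ± 0.04). Their list mean did not pass on all 24 arrays (adjusted p = 0.0501), but passed without the arrays at CT 40, CT 62 and CT 64 (0.0134), with the median of members (0.0467), with the oligodendrocyte marker covariate (0.00567) and with the array background covariate (0.0290). At a threshold of 0.01 on the adjusted p of genes, 2 members were called and the enrichment was lost (0.107).

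Glucocorticoid-induced genes were called with peaks on either side of the change from subjective day to night. Tsc22d3, a mediator of glucocorticoid action, peaked at 14.1 h (amplitude 0.25 ± 0.03), the metallothioneins Mt1 at 11.9 h (0.19 ± 0.03) and Mt2 at 9.02 h (0.23 ± 0.04), and the transcription factor Klf15 at 11.5 h (0.19 ± 0.03). Of 17 members 7 were called and 12 adjusted over the list alone (Fisher's exact adjusted p = 0.000824), and the list mean had an amplitude of 0.16 ± 0.04 with a peak at 13.2 h (permutation p = 0.00083, adjusted p = 0.00332). The 7 peaks were not significantly closer together than those of random sets of rhythmic genes (adjusted p = 0.152). Of the 7, 3 peaked between 6 and 12 h and 4 between 12 and 18 h, the window that holds the 3 arrays of narrow range. The count was 9 of 17 without those arrays and 10 of 17 with the array background covariate.

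**Figure D2:**
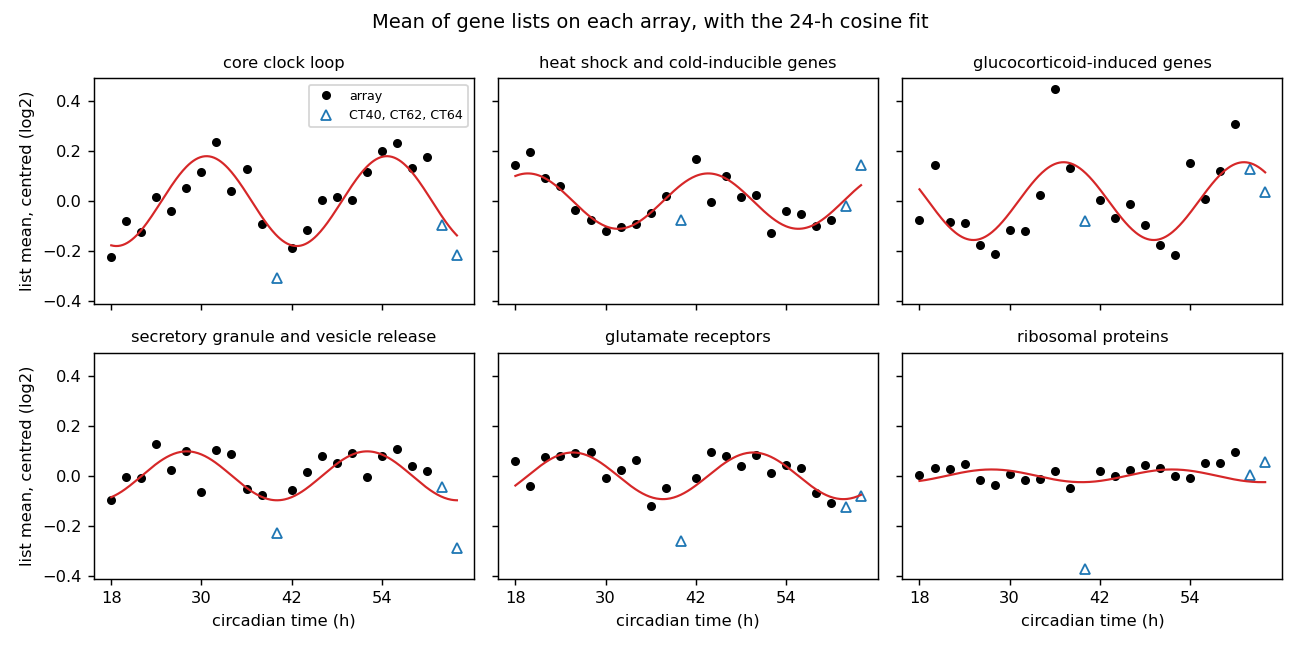
Mean of centred log2 values over the members of 6 gene lists (vertical axes) against circadian time in hours, 1 point per array and the 24-h cosine fit as a line, with open triangles for the arrays at CT 40, CT 62 and CT 64. The heat shock mean peaks at 19.7 h and the core clock mean at 6.68 h.

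In the fit on all arrays, some genes of GABA and glutamate transmission were called rhythmic, with peaks in the first hours of the subjective day. Gad2 and Gad1, which encode the enzymes of GABA synthesis, peaked at 2.58 and 2.99 h (amplitudes 0.15 ± 0.03 and 0.20 ± 0.04), and the receptor subunit gene Gabrb1 and the chloride exporter gene Slc12a5 at 1.25 and 2.68 h. The glutamate receptor genes Grin2b, Gria2, Grin3a and Grm5 peaked between 0.870 and 2.54 h with amplitudes of 0.11 to 0.18. All 8 of 20 GABA genes called (11 adjusted over the list alone; Fisher's exact adjusted p = 0.000436) and all 8 of 18 glutamate receptor genes called (9 adjusted over the list alone; adjusted p = 0.000232) peaked before 6 h, closer together than random sets of rhythmic genes (adjusted p = 0.0140 and 0.0217). The list means peaked at 2.16 h (amplitude 0.10 ± 0.02, adjusted p = 0.00179) and 1.64 h (0.09 ± 0.02, adjusted p = 0.00084).

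The 3 arrays of narrow range lie opposite to these peaks, and fewer of these genes were called without them or with the array background covariate. Other sets of 3 arrays were not left out for these lists. The loss of calls without these arrays was therefore not told apart from the loss of any 3 arrays. Without those arrays 3 GABA genes and 0 glutamate receptor genes were called by limma (7 glutamate receptor genes at an unadjusted p under 0.05). Adjusted over the list alone the counts were 9 and 5, and neither list was enriched (adjusted p = 0.152 and 1). With the array background covariate limma called 1 and 0 (4 glutamate receptor genes at an unadjusted p under 0.05), and 5 and 0 adjusted over the list alone (adjusted p = 0.759 and 1). None of the 8 genes named here stayed called with it. When single arrays were left out, Slc12a5, Gria2, Grin3a and Grm5 lost their calls in 2, 5, 3 and 12 fits (adjusted p up to 0.0525 without CT 64, 0.0611 without CT 36, 0.0649 without CT 64 and 0.0940 without CT 62). At a threshold of 0.01 both counts were 0, and with no filter on dim genes 2 glutamate receptor genes were called (adjusted p = 0.350). The glutamate receptor mean stayed rhythmic in both settings (amplitudes 0.07 and 0.06, adjusted p = 0.00672 and 0.0368), and the GABA mean stayed so without the 3 arrays (amplitude 0.06, adjusted p = 0.0150) but not with the covariate (amplitude 0.05, adjusted p = 0.0813).

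Ion channels of SCN neuron firing had 7 of 29 genes called and 11 adjusted over the list alone (Fisher's exact adjusted p = 0.0147). They included the calcium channel genes Cacna1g (2.88 h, amplitude 0.21 ± 0.03) and Cacna1a (2.64 h, 0.13 ± 0.03), the potassium channel gene Kcnc2 (5.13 h, 0.26 ± 0.05) and the sodium channel gene Scn8a (2.89 h, 0.17 ± 0.04). Of the 7, 5 peaked before 6 h and 2 between 18 and 24 h (adjusted p of the concentration 0.152). The list mean peaked at 2.53 h (amplitude 0.07 ± 0.01, adjusted p = 0.00179). Secretory granule and vesicle release genes had 8 of 25 called and 13 adjusted over the list alone (adjusted p = 0.00177). Vgf, a granule peptide precursor, peaked at 5.66 h (amplitude 0.29 ± 0.05), and Syt4, Cadps and Syt5 between 1.06 and 5.61 h. Their mean peaked at 4.05 h (amplitude 0.10 ± 0.02, adjusted p = 0.00275). G protein and cAMP signalling genes had 9 of 33 called and 11 adjusted over the list alone (adjusted p = 0.00209). Pde10a and Pde2a, which encode phosphodiesterases, peaked at 4.10 h (amplitude 0.31 ± 0.04) and 3.78 h (0.33 ± 0.05), while 3 of the 9 peaked between 12 and 24 h. Their mean peaked at 1.99 h (amplitude 0.07 ± 0.02, adjusted p = 0.0180). The concentration of peaks did not pass for the secretory list (adjusted p = 0.3004) or the G protein list (0.590).

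The means of these lists too peaked opposite to the 3 arrays of narrow range. Without those arrays the secretory list was no longer enriched (4 called, adjusted p = 0.0792) and the means of the secretory and G protein lists lost their calls (adjusted p = 0.0587 and 0.0763). With the array background covariate the ion channel list (3 called, adjusted p = 0.274) and the secretory list (3 called, adjusted p = 0.214) were no longer enriched, and the G protein mean lost its call (adjusted p = 0.445). The ion channel mean kept its call in both settings, at amplitudes of 0.04 and 0.04 (adjusted p = 0.0352 and 0.0425). At a threshold of 0.01 only 1 ion channel gene and 1 secretory gene were called (adjusted p = 0.645 and 0.616). Cacna1a, Scn8a, Syt4 and Cadps were not called with the covariate (adjusted p from 0.0691 to 0.183), and Scn8a and Syt4 not without the 3 arrays (0.142 and 0.0963).

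Among genes of metabolism and the cell cycle, few were called. Of 40 mitochondrial respiratory chain genes 5 were called, 5 also adjusted over the list alone (adjusted p = 0.428). Sdha and Atp5a1 peaked at 2.04 and 2.40 h, and Ndufa2 and Uqcrb at 14.1 and 14.6 h. Without the 3 arrays of narrow range limma called 0 of the 40 (12 at an unadjusted p under 0.05) and 0 adjusted over the list alone. Both counts were again 0 with the array background covariate (6 unadjusted). Each of these 4 genes also lost its call in 1 to 4 fits that left out 1 array (adjusted p up to 0.0502 for Sdha, 0.0597 for Ndufa2 and 0.0543 for Uqcrb without CT 62 and 0.0601 for Atp5a1 without CT 64). The list mean had an adjusted p of 0.446. Of 18 cholesterol synthesis genes Dhcr7 alone was called, at 5.11 h with an amplitude of 0.14 ± 0.04 (1 adjusted over the list alone; adjusted p of the enrichment 1). It lost its call without the 3 arrays (adjusted p = 0.170), with the array background covariate (0.0796) and in 15 fits that left out 1 array (0.0871 without CT 54). The mean of that list passed with the oligodendrocyte marker covariate alone (adjusted p = 0.0144, against 0.549 without it). Of 18 cell cycle and DNA damage genes 2 were called (4 adjusted over the list alone; adjusted p of the enrichment 0.784). These were the repair gene Xpa at 9.17 h (amplitude 0.17 ± 0.03) and the cell cycle inhibitor Cdkn1b at 15.1 h (0.29 ± 0.07), which was not called with the array background covariate (adjusted p = 0.162). A second probe set of Cdkn1b was not called (peak 0.05 h, adjusted p = 0.0848). The mean of this list peaked at 13.5 h (amplitude 0.03 ± 0.01, adjusted p = 0.0429). That call ended without the arrays at CT 40, CT 62 and CT 64 (0.0506), with the median of members (0.0605), with linear time (0.0553) and with the oligodendrocyte and meningeal marker covariates (0.0707 and 0.0608).

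Few markers of other cell types were called. The astrocyte genes Fabp7, a fatty acid binding protein (3.50 h, amplitude 0.46 ± 0.05), and Aldoc (2.41 h, 0.29 ± 0.07) were the 2 called of 16 (3 adjusted over the list alone). Aldoc lost its call without the 3 arrays of narrow range (adjusted p = 0.126), with the array background covariate (0.331) and in 6 fits that left out 1 array (0.0680 without CT 62). Single genes were called among 7 oligodendrocyte precursor markers (Neu4, 15.03 h), 17 endothelial and mural cell markers (Cldn5, 23.2 h) and 11 ependyma and tanycyte markers (Rsph1, 23.9 h), each 1 adjusted over the list alone. None of these 3 genes was called with the array background covariate (adjusted p from 0.0718 to 0.125), Neu4 was not without the 3 arrays (0.0907), and Rsph1 lost its call in 13 fits that left out 1 array (0.0780 without CT 36). By limma 0 of 15 oligodendrocyte and myelin markers, 0 of 16 microglia markers, 0 of 11 meningeal fibroblast markers, 0 of 6 choroid plexus markers, 0 of 20 markers of neighbouring hypothalamic neurons, 0 of 53 ribosomal protein genes and 0 of 37 proteasome genes were called. Adjusted over the list alone the counts were 0 in each of these lists. At an unadjusted p under 0.05 these lists had 3, 1, 3, 0, 2, 7 and 4 genes, with the smallest p for Sox10, Aif1, Col3a1, Kl, Trh, Rps14 and Psmb10 (0.00920, 0.0339, 0.0119, 0.0968, 0.00893, 0.00601 and 0.00974). Of 3 red blood cell markers limma called 0 (1 at an unadjusted p under 0.05, Alas2 at 0.00758) and 1 adjusted over the list alone. None of these lists was enriched or depleted (adjusted p from 0.0832 for the ribosomal proteins to 1). Depletion could hardly be seen, since only 0.23 (red blood cell markers) to 4.05 (ribosomal proteins) called genes were expected. None of the means of these lists was rhythmic (adjusted p from 0.108 to 0.964). The astrocyte mean did pass with the oligodendrocyte (adjusted p = 0.00027) and meningeal marker covariates (0.00162), and the means of oligodendrocyte markers (0.0290) and their precursors (0.0425) with the array background covariate. The oligodendrocyte markers differed without the arrays at CT 40, CT 62 and CT 64, with 4 called and 10 adjusted over the list alone (Fisher's exact adjusted p = 0.0153). With the array background covariate they had 8 called and 15 adjusted over the list alone (adjusted p = 1.55e-07).

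In all, limma called 1067 of 13956 genes at an adjusted p under 0.05, and 170 at 0.01. Their amplitudes ran from 0.09 to 0.73 with a median of 0.16, and 1007 of them changed less than 1.5-fold from trough to peak. The 7 other periods between 48 and 6 h tried gave 0 genes each by limma when fitted alone, with 2212 genes at an unadjusted p under 0.05 for 12 h and 243 to 480 for the rest, against 3835 at 24 h. The count was 704 without CT 28, 679 without CT 40, CT 62 and CT 64 together (494 of the same genes) and 534 with the array background covariate (339 of the same genes). When 99 other sets of as many arrays, drawn at random, were left out, the median count was 555. The fall to 679 was therefore not larger than that of a typical set. The count on all arrays rose to 1988 and 3330 with the meningeal fibroblast and oligodendrocyte marker covariates.

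Of the rhythmic genes 610 (57.2%) peaked between 0 and 6 h, 93 between 6 and 12 h, 217 between 12 and 18 h and 147 between 18 and 24 h, with a mean direction at 2.32 h and a resultant length of 0.383. Besides the GABA and glutamate lists, none of the other 12 lists with at least 3 rhythmic genes passed the test of concentrated peaks (adjusted p from 0.152 to 0.947). That test was run only on the calls from all 24 arrays. The distribution of all peaks moved with the arrays of narrow range. Without CT 40, CT 62 and CT 64 the share between 0 and 6 h was 25.3% and the mean direction 20.2 h, and with the array background covariate they were 15.5% and 13.7 h. At an adjusted p under 0.01 the share was 36.5%.

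**Figure D3:**
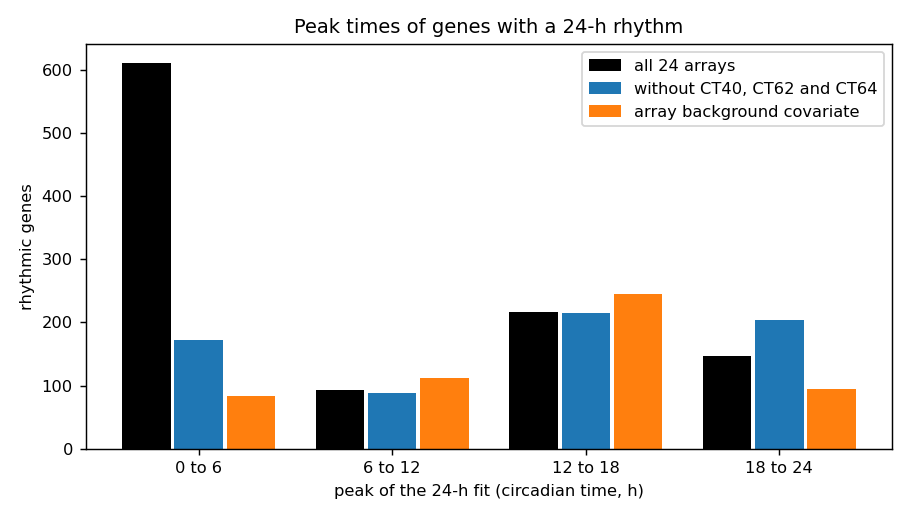
Number of rhythmic genes (vertical axis) by 6-h window of peak circadian time in hours (horizontal axis), as bars for all 24 arrays, for 21 arrays without CT 40, CT 62 and CT 64, and with the array background covariate. The window from 0 to 6 h holds 610, 172 and 83 genes.

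The second comparison asked what changed between the first and the second sampled cycle at the same circadian times. No gene passed the test in limma, with 0 of 13956 genes called and 1216 at an unadjusted p under 0.05. The potassium channel genes Kcna4 and Kcnt1 came closest with the Polycomb gene Phc3. Kcna4 differed by -0.26 ± 0.05 (second minus first, adjusted p = 0.146, higher in 1 of 12 pairs), Phc3 by -0.24 ± 0.05 (adjusted p = 0.160, higher in 1 of 12 pairs) and Kcnt1 by 0.21 ± 0.04 (adjusted p = 0.160, higher in 12 of 12 pairs). Of the 28 gene lists 0 shifted after adjustment in the exact paired sign-flip test, and 4 had an unadjusted p under 0.05. The core clock mean differed by 0.05 (SD 0.05, higher in 9 of 12 pairs, exact p = 0.00977, adjusted p = 0.273), the SCN identity mean by 0.05 (SD 0.08, 10 of 12 pairs, exact p = 0.0415, adjusted p = 0.284), the ribosomal protein mean by 0.06 (SD 0.12, 8 of 12 pairs, exact p = 0.0200, adjusted p = 0.280) and the mitochondrial mean by 0.04 (SD 0.06, 10 of 12 pairs, exact p = 0.0352, adjusted p = 0.284). The largest difference was that of the meningeal fibroblast markers, 0.30 (SD 0.47, 9 of 12 pairs, exact p = 0.0508, adjusted p = 0.284). The count of genes was 5 with array weights, 1 without CT 54 and 66 with the array background covariate.

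The third comparison asked whether rhythms changed in amplitude or phase from the first cycle to the second. Per2 peaked at 9.41 h in the first cycle and 9.65 h in the second, and Dbp at 7.33 and 7.26 h. Other clock genes moved more, Per1 from 5.31 to 7.11 h, Ciart from 7.06 to 8.71 h, Nr1d2 from 6.996 to 5.32 h and Tef from 9.20 to 7.54 h, in both directions. By limma 0 of 13956 genes differed (338 at an unadjusted p under 0.05), and the lowest p were those of Lrrc2, C130023O10Rik and Hjv (unadjusted p = 0.000247, 0.000401 and 0.000471, adjusted p = 0.9999 for each). Of the 28 list means 0 differed in rhythm between the cycles in a paired sign-flip permutation test (0 at an unadjusted p under 0.05, adjusted p from 0.708 to 1).

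The last comparison asked for 12-h rhythms beside the 24-h one. Rasgrf2, an exchange factor for Ras and Rac, had a 12-h amplitude of 0.23 ± 0.04 with a first peak at 9.81 h, and Ube2ql1, a ubiquitin-conjugating enzyme, 0.17 ± 0.03 at 10.8 h. The other called genes were Gm1043 (0.21 ± 0.04), Synb (0.20 ± 0.03) and Gm10142 (0.20 ± 0.03), with first peaks between 3.24 and 3.53 h. These 5 of 13956 genes passed in limma at an adjusted p of 0.0412 each, with 3061 at an unadjusted p under 0.05. The count was 0 with no filter on dim genes, with quantile normalization, without the arrays at CT 40, CT 62 and CT 64 and with the array background covariate, and it ranged from 0 to 9 when single arrays were left out.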

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

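Probe sets outside the gene test also carried 24-h rhythms. Of 1151 probe sets listed with several gene symbols and above the filter 22 were called rhythmic (1.91%), and 7 with the array background covariate, a setting chosen after seeing the data. Of 6192 probe sets above the filter that the annotation does not list 6 were called (0.10%), and 1 with that covariate.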

How the results depend on the processing

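The fits without CT 40, CT 62 and CT 64 and those with meningeal, pituitary or array background covariates were chosen after seeing the data, as were the covariate fits and single-array fits of the peak times. The count of 24-h rhythmic genes (1067) stayed within 1.5 times under 15 alternatives, from 763 with the pituitary marker covariate to 1570 with array weights. It was 3330 with the oligodendrocyte covariate, 1988 with the meningeal covariate, 3149 with both, 679 without CT 40, CT 62 and CT 64, 534 with the array background covariate, 2184 with 24-h and 12-h terms together, and 16 and 81 in the first and second cycle alone, which hold fewer samples. Leaving out single arrays gave 704 (CT 28) to 1440 (CT 30). The median count was 555 over 99 other random sets of as many arrays as CT 40, CT 62 and CT 64.

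The count between cycles was 5 with array weights, 66 with the array background covariate and 0 to 1 (CT 54) with single arrays left out. The change in rhythm gave 0 genes under every alternative run, at single arrays too. The 12-h count (5) was 0 with no filter, all probe sets, quantile normalization, the oligodendrocyte, meningeal, both, pituitary or array background covariates, linear time, and without CT 40, CT 62 and CT 64. It was 8 at the 50th percentile filter and with a trended prior, 11 with median centring, and 0 to 9 (CT 22 and CT 40) with single arrays left out.

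The share of peaks before 6 h (57.2%) was 36.5% at an adjusted p under 0.01, 50.6% with no filter, 25.3% without the 3 arrays, 15.5% with the array background covariate, 63.0% and 63.3% with the oligodendrocyte and meningeal covariates, and 46.2% (CT 40) to 60.8% (CT 30) with single arrays left out. Lists with a rhythmic mean fell from 11 to 7 without the 3 arrays, and enriched lists from 10 to 6 at a gene threshold of 0.01. List enrichment was lost, with 0 called where fewer than 1 was expected, for GABA genes (0 at 0.01) and glutamate receptors (0 at 0.01, 0 without the 3 arrays, 0 with the background covariate). Oligodendrocyte markers gained it (4 called without the 3 arrays, 8 with the covariate). Of the other list results 347 kept their side of the threshold, 24 lost it and 13 gained it.

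Of 77 named rhythmic genes 59 stayed called without the 3 arrays, 52 with the background covariate, 68 with the pituitary covariate and 69 to 77 under the other alternatives on all 24 arrays; 13 and 25 were called in the first and second cycle alone. None changed phase by more than 6 h. With single arrays left out 64 kept every call and 13 lost at least 1: Aldoc, Atp5a1, Avp, Dhcr7, Gria2, Grin3a, Grm5, Ndufa2, Ppp1ca, Rsph1, Sdha, Slc12a5 and Uqcrb, with a highest adjusted p of 0.0940 (Grm5 without CT 62). Except where a setting holds fewer samples, the cause was not tested. Simulated 24-h rhythms of amplitude 0.15, near the median of the called genes, were recovered in 46.3% of cases, in noise independent between genes.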

Other observations

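The tests here were chosen only after the results were seen, except those of the interferon-induced genes against array background and meningeal tissue, which were set before their results were seen. Some genes induced by interferon, part of the antiviral response, had 24-h rhythms with peaks in the early subjective night. Of 24 such genes 8 were called (Fisher's exact p = 0.000276) and 16 were not, among them Cmpk2 (3.08 h), Lgals3bp (7.96 h), Irf9 (19.4 h) and Stat2 (22.2 h). Ifit3 changed 2.42-fold with a peak at 14.1 h, Ifit1 had an amplitude of 0.34 ± 0.08 (15.3 h), Bst2 0.24 ± 0.05 (14.23 h), Oas1a 0.22 ± 0.05 (13.98 h), Ifi27 0.18 ± 0.04 (15.4 h) and Ifit2 0.16 ± 0.04 (15.4 h). The list mean had an amplitude of 0.16 ± 0.03 and a peak at 14.7 h (permutation p = 7e-05), with 0.20 and 15.1 h in the first cycle and 0.12 and 13.95 h in the second. The list was added because Ifit3, Ifit3b and Ifi27l2a were among the called genes of largest amplitude, and without these 3 the amplitude was 0.10 ± 0.03 (p = 0.0027, 5 of 21 genes called, Fisher's exact p = 0.0188).

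The peak of the interferon-induced genes lies at the circadian times of the 3 arrays of narrow range, but the list mean kept its rhythm with the array background covariate (permutation p = 0.00016, amplitude 0.18) and without those arrays (p = 2e-05, amplitude 0.19, 9 genes called). The rhythm without Ifit3, Ifit3b and Ifi27l2a was weaker (p = 0.00701 and amplitude 0.11 with the covariate, 0.00113 and 0.12 without the arrays), with amplitudes of 0.145 and 0.06 in the first and second cycle, and these values argue against array background as the whole cause. The list mean also kept its rhythm with the meningeal marker covariate (permutation p = 6e-05, amplitude 0.13; 0.00478 and 0.08 without the 3 genes) and the oligodendrocyte marker covariate (permutation p = 3e-05, amplitude 0.14; 0.00365 and 0.08). A 24-h rhythm of interferon-induced transcripts in the dissected tissue may remain as a hypothesis, found and tested on the same data. The oligodendrocyte marker mean itself peaked at a like time with the array background covariate (amplitude 0.27, 13.996 h, adjusted p = 0.0290) and without the 3 arrays (0.22, 14.97 h, 0.0587), and other cell types, such as microglia (list mean adjusted p = 0.919), were not tested as covariates.

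Another pattern is the large group of 610 genes with a peak between 0 and 6 h. With the array background covariate 89 of them stayed called, so array background may account for many of these calls. Without CT 40, CT 62 and CT 64, 187 of them stayed called. CT 40 falls at circadian time 16 of the first cycle and CT 62 and CT 64 at 14 and 16 of the second, so the covariate shares variation with time of day and can remove true rhythms of opposite phase as well. Of 100 sets of 3 arrays left out, only 1, that of CT 40, CT 62 and CT 64, gave a share before 6 h as low as 25.3% (lowest other 32.4%, median of the others 49.0%). The other sets were drawn at random, so loss of 3 arrays at random times is argued against as the cause of this low share. They were not matched on time of day, so they cannot tell array background from the loss of any arrays at circadian times 14 and 16. The number of genes with a peak before 6 h was 172 without CT 40, CT 62 and CT 64. Its median over the other sets was 268, and their lowest number was below 172. The fall in number was therefore not told apart from the loss of 3 arrays at random times. Meningeal tissue is argued against, since 595 of the 610 stayed called with its marker covariate, though calls as a whole rose from 1067 to 1988 in that setting. A biological rhythm stays open for all of the 610 genes, whether or not they kept their calls.

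Growth hormone and prolactin, hormones of the anterior pituitary, were high in a few early arrays: the pituitary marker mean, centred over the arrays, lay between 0.65 and 2.15 from CT 18 to CT 26, between -0.53 and 0.09 in the other 7 arrays of the first cycle, and between -0.66 and 0.41 in the second. Gh, chosen after its values were seen, had a mean log2 value of 7.77 in the first cycle and 5.48 in the second, a difference of -2.29 ± 0.48 that did not pass (adjusted p = 0.160, higher in the second cycle in 2 of 12 pairs), and Prl differed by -1.16 ± 0.32 (adjusted p = 0.393, 4 of 12 pairs). Across the 24 arrays Prl followed Gh (Pearson r = 0.935, permutation p = 1e-05, the smallest possible; Spearman rho = 0.809, permutation p = 2e-05), with r = 0.914 without CT 20 and CT 22, the farthest from the median of Gh, and 0.946 and 0.721 within the first and second cycle. The pituitary marker list was added because of Gh and holds it, so its mean (-0.81, SD 0.86, 2 of 12 pairs higher, exact p = 0.00293, 24-h permutation p = 0.0337) rests on Gh and Prl, and the other 3 genes gave a mean of -0.20 (SD 0.27, 3 of 12 pairs, exact p = 0.0259), with Pomc, which hypothalamic neurons also transcribe, at -0.58 ± 0.18, Lhb at -0.04 ± 0.05 and Ghrhr at 0.03 ± 0.05. Carry-over of pituitary tissue in some samples may explain the shared course of both hormones, and no biological explanation was tested.

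Other orders of the sampling times and other splits of the arrays gave these counts. For 24-h rhythms 1 of 100 orders, the real one, gave 1067 genes and the highest other order gave 1. These values argue against a chance order of the arrays as the source of the count as a whole. They do not test single genes. The other orders scatter CT 40, CT 62 and CT 64, so they cannot tell whether the place of these arrays in the day raised the count. With the array background covariate 339 of the 1067 genes stayed called. For 12-h rhythms 3 of 100 orders, the real one included, gave at least the 5 genes seen, and the highest other gave 121. The count was 0 under 10 of the 14 alternatives that did not leave out a single array, so chance is not taken as excluded for these genes. An order with so many genes may reflect a structure of the samples, which was not tested. At an unadjusted p under 0.05 the moderated F test of 12-h terms gave 3061 genes on all 24 arrays. It gave 868 with the array background covariate and 1412 without CT 40, CT 62 and CT 64, so the count fell in both settings. Other sets of 3 arrays were not left out for the 12-h count. The changes between cycles and in rhythm had 0 genes, a count that 100 of 100 splits must reach, so these splits carry no information on chance (highest other 0 and 5).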
